A study of Mus musculus with 93 samples.

How the data were processed

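The series holds 93 bulk SMART-Seq2 libraries of sorted mouse EMP, pMac and Mac, and each library was assigned to 1 of 46 groups from its labels (cell type, tissue and age). The labels name polyA RNA and SMART-Seq2 and give replicate numbers, and per the series description the replicates are both technical and biological, without saying which. All libraries were therefore treated as separate samples, and p-values measure the spread between them.

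The deposited values are on a log2 scale, with 1 value per Ensembl transcript and library, per the file headers and the range of the values (0.836 to 19.0). The authors had already normalized and log-transformed them, and how is not given in the sources used here. The base of 2 was inferred from that range. Bowtie 1.1.1, DESeq2 and the mm10 build are named in the submitters' processing notes without their roles. The file has no counts, so the depth per library and the counting error are unknown.

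Each library's lowest values form a narrow band whose place differs between libraries, from 2.33 to 4.88. A common floor of 5.38, which is 0.5 above the highest band, was applied to all libraries, and a transcript at or under it was treated as not detected. Between 14411 and 25138 transcripts per library (median 22606 of 37521) lay above the floor. A limit of 18000 transcripts, set after the values were seen and before any fit, marked 9 libraries as having few detected transcripts: kidney P2 replicates 1 and 2, liver P2 replicate 1, P8 replicate 2 and P21 replicates 1 and 2, and lung P2, P8 and P21 replicate 2.

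Of the 37521 transcripts, 36703 were matched by identifier to a gene symbol in the mm10 reference annotation and 818 were not. For each of 14181 genes, the part of its transcripts' values above the floor was summed on the linear scale, the floor was added, and the sum was returned to log2. Levels are thus bounded below by 5.38, and a gene at that level is not detected. Genes with near-identical copies, such as Hba-a1 and Hba-a2 or Hbb-bs and Hbb-bt, cannot be separated with certainty.

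The small offsets of transcripts within the band are shared by sets of libraries. Clustering of their correlations over 3992 transcripts gave a larger set of 60 and a smaller set of 33 libraries, with a median correlation of 0.159 within the larger, 0.714 within the smaller and -0.334 between the sets. The number of sets was preset and is not a result of the clustering. Each transcript's median over libraries was removed first, which favours negative correlations between sets. With its low correlation, the larger set may itself be mixed. The labels name no such sets. All 13 pMac libraries, 1 of 6 EMP and 19 of 74 Mac libraries are in the smaller set, and 3 libraries were closer to the other set than to their own.

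Differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. The plan was written before the data were examined and foresaw counts with a fallback to limma on log2(value + 1). Since the values were already on a log2 scale, they were used without a further transform. A gene was tested if its level was at least 6.38 in as many libraries as the smallest group compared, and at least 2. A gene was called if its Benjamini-Hochberg adjusted p was under 0.05 and its log2 difference at least 1 in size. Stages were compared in a fit of all EMP, all pMac and the Mac of E10.25 and E10.5 with tissue group as a covariate. Tissues were compared in additive fits of age and tissue, each tissue against the unweighted mean of the others, for Mac of E10.25 and E10.5 and for Mac of E14.5 to P21. pMac of E9.5 were compared between tissues with an F test. The time course in brain and liver used 1 mean per tissue and age, with an interaction contrast for the difference between them.

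Gene lists for macrophage functions, tissue macrophages, cell cycle and other cell types that a sort could hold were written before the data were examined. Each was tested with fry in limma, which asks whether its genes move on balance one way, with p-values adjusted over all lists of a comparison. As alternatives, camera was run with a preset correlation between genes of 0.01 and with an estimated correlation. Camera asks another question, whether the genes of a list differ more than the other genes tested, whereas fry tests the list by itself. Since fry also allows for correlation between genes, a call lost in camera need not be due to that correlation. Adjusted p-values given with an estimated correlation are those of camera. Counts of called members are given over all genes tested and adjusted over the list alone. Lists of tissue macrophage markers may hold genes that the study itself chose on these samples, so they are not independent evidence of their direction.

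The genes named in the text follow a rule fixed beforehand. For each comparison these are the 5 called genes with the largest rise and the 5 with the largest fall among those with a mean of at least 7.35 in the higher group, a level set from the median library total, and no predicted or clone name, up to 4 called members of each list, and a fixed set of marker genes. Some genes that meet this rule are not reported here. Levels of E12.5 libraries, tissue-cell genes and genes in reads shared between libraries were chosen after their values were seen.

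The fits were tested on simulated data, with the real genes' means and spreads and 200 genes with a mean of at least 8 changed by known amounts, 50 per amount. Of rises of 3 on the log2 scale, 94% were recovered for pMac against EMP (11591 genes), 100% for early Mac against pMac, 92% for brain and 90% for lung at E14.5 to P21 (11788 genes), 76% for P21 against E14.5, and 88% for brain at E10.25 to E10.5 (11288 genes). Of falls of 3, the shares were 96%, 100%, 92%, 82%, 64% and 82% in the same order. In the time course fit (13647 genes) the share was 6% for brain and 8% for liver of rises of 3 and 16% and 14% of falls, and of rises of 5 it was 60% and 48%. For the difference between brain and liver it was 0% of rises of 3, 2% of falls of 3 and 18% of rises of 5. Many real changes in this fit were thus not detectable.

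Library values were compared for repeats. Pairs of libraries of 1 group had a median correlation of 0.765 (0.493 to 0.965), against 0.625 between groups, and 7 groups had 1 library. At most 0.0226% of detected genes had identical values in 2 libraries.

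Alternatives fixed beforehand were no filter on low values, a single mean value per group, replicate numbers as a block, leaving out each library in turn, other samples or covariates for the stage comparisons, 1 mean per tissue and age, and only the 4 groups compared in the time course. Added after seeing the data were values as deposited without the common floor, the transcript with the highest mean in place of the sum, the same number of highest transcripts in every library (14411), centring of each library on genes detected in at least 80% of libraries (6667) or in all (1221), the sample set as a covariate, each set alone, and omission of the 9 libraries with few detected transcripts. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.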

Results

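RNA from sorted mouse cells was sequenced with SMART-Seq2, a full-length protocol for small amounts of RNA, in 93 libraries that fall into 46 groups by cell type, tissue and age. The cell types are EMP (erythro-myeloid progenitors, 6 libraries), pMac (the precursor stage between EMP and macrophage, 13 libraries) and Mac (macrophages, 74 libraries). EMP came from yolk sac at E9 (n = 2) and E10.25 (n = 2) and from liver at E10.25 (n = 2). pMac came at E9.5 from brain (n = 4), the caudal part of the embryo (n = 3) and yolk sac (n = 2), and at E10.25 from brain, limbs, liver and yolk sac (n = 1 each). Mac covered brain, limbs, liver and yolk sac at E10.25 and E10.5, brain, limbs and liver at E12.5, and brain, kidney, liver, lung and skin from E14.5 to P21, with 1 to 4 libraries per group. The values are on a log2 scale without counts, so sequencing depth is unknown. Between 14411 and 25138 transcripts per library (median 22606) lay above a common floor of 5.38, the level below which values were treated as not detected. The count was under 18000 in 9 Mac libraries, all of kidney P2, lung P2 to P21 or liver P2 to P21. Small offsets shared by libraries were used to divide them, with a preset number of sets, into a larger set of 60 and a smaller set of 33. All 13 pMac libraries are in the smaller set.

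Errors after log2 differences are standard errors of the limma fit, and errors after levels are standard deviations (SD) between libraries. The size of a difference from a group at the floor depends on where the floor lies. The balance of higher and lower genes in a comparison can depend on how the libraries are scaled, as given further below. p-values measure the spread between libraries, which may be technical, since the series holds both technical and biological replicates and the labels do not tell them apart. Positions are those of the mm10 reference annotation, in which the genes named most often in the text are protein-coding. Kit (ENSMUSG00000005672.12) lies on chromosome 5 from 75574916 to 75656722 on the plus strand, and Csf1r (ENSMUSG00000024621.16) on chromosome 18 from 61100598 to 61132149, also on the plus strand. Sall1 (ENSMUSG00000031665.7) lies on chromosome 8 from 89027235 to 89044162 and Clec4f (ENSMUSG00000014542.3) on chromosome 6 from 83644542 to 83656187, both on the minus strand. Id3 (ENSMUSG00000007872.3) lies on chromosome 4 from 136143497 to 136145755 and Pparg (ENSMUSG00000000440.12) on chromosome 6 from 115360951 to 115490399, both on the plus strand. Cd207 (ENSMUSG00000034783.7) lies on chromosome 6 from 83671215 to 83677857 on the minus strand.

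The step from EMP to pMac was compared first. Lpl, which encodes lipoprotein lipase, had the largest rise, by 5.56 ± 0.53 on the log2 scale, from 7.84 ± 1.52 in EMP (n = 6) to 13.09 ± 0.65 in pMac (n = 13; adjusted p = 1.64e-10). The lysosomal protease Ctss rose by 5.12 ± 0.66, the complement component C1qb by 5.03 ± 0.48 and the oxidase subunit Cybb by 4.98 ± 0.60. Csf1r, the receptor for the macrophage growth factor CSF1, rose by 3.14 ± 0.36 (adjusted p = 2e-08), and the chemokine receptor Cx3cr1 by 3.82 ± 0.44. Mycn, a growth-promoting transcription factor, fell most, and decreased by 4.04 ± 0.53, from 10.10 ± 0.59 to 5.91 ± 0.94. Kit, the stem cell factor receptor of progenitors, fell by 3.81 ± 0.62 (adjusted p = 2.79e-05) and the progenitor factor Gata2 fell by 3.56 ± 0.56. The cells were sorted, and genes of the sort markers were not left out of the genes or lists tested. A surface marker used in the sort would differ between stages by design, in this step and the next.

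Of the macrophage core list, 21 of 23 measured members (21 adjusted over the list alone) rose, among them C1qb, C1qc (4.39), Mrc1 (4.33) and Cx3cr1. The transcription factor Maf (3.19) and the F4/80 gene Adgre1 (2.53) rose with them, whereas Spi1, the general myeloid factor PU.1, differed by 0.52 ± 0.39 (adjusted p = 0.557). Phagocytic and complement receptors rose in 8 of 16 (12 adjusted over the list alone), led by C3ar1 (4.93) and Fcgr1 (3.50). Pattern recognition receptors rose in 8 of 18 (9 adjusted over the list alone), with the scavenger receptor Msr1 at 4.29. Of the cytokine and chemokine receptors, 7 of 23 (13 adjusted over the list alone) rose and 1 fell. Of the progenitor list, 4 of 12 measured members (6 adjusted over the list alone) fell, including Mycn, Kit, Gata2 and Hoxa9 (fell by 2.49). Endothelial genes fell in 4 of 8 (6 adjusted over the list alone), among them Esam (-2.78), a junction gene that progenitors also express. The erythroid factor Gata1 fell by 2.94 and the cytokine receptor Flt3 fell by 1.98, though within the smaller set, where 1 EMP library is left, it was 0.37 higher in pMac, and its call ended in 2 of the 39 fits that leave out 1 library. The calls of these 6 lists hold in camera with an estimated correlation between genes. Its adjusted p ran from 3.96e-04 for the endothelial list to 0.034 for the cytokine and chemokine receptors. Camera compares a list with the other genes, here and wherever an estimated correlation is named. The mast cell list fell in 3 of 4 (3 adjusted over the list alone), with a median difference of -2.81 against -1.44 for the progenitor list (adjusted p = 0.0088 with an estimated correlation). The 3 genes were Kit and Gata2, which both lists hold, and Cpa3 (fell by 2.07). The list averaged 8.26 to 9.30 in the EMP groups and 5.38 to 6.41 in the pMac groups other than liver, where 1 library was at 8.42. The megakaryocyte list fell in 2 of 5 (2 adjusted over the list alone) (adjusted p = 0.125 with an estimated correlation). The interferon response list rose in 5 of 16 (12 adjusted over the list alone), with adjusted p = 0.0613 with an estimated correlation. No member of the 25 measured cell cycle genes passed the test.

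In all, 646 of 11591 genes tested passed an adjusted p of 0.05 with a log2 difference of at least 1, 425 higher and 221 lower in pMac, in a limma fit of 39 libraries with tissue group as a covariate. Of the 6 EMP libraries, 5 are in the larger sample set, so stage and set are largely shared. With the set as a covariate the count was 177, within the smaller set (1 EMP library) it was 8, and the larger set holds no pMac. At E10.25 only the count was 339, and in yolk sac alone 69.

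**Figure D1:**
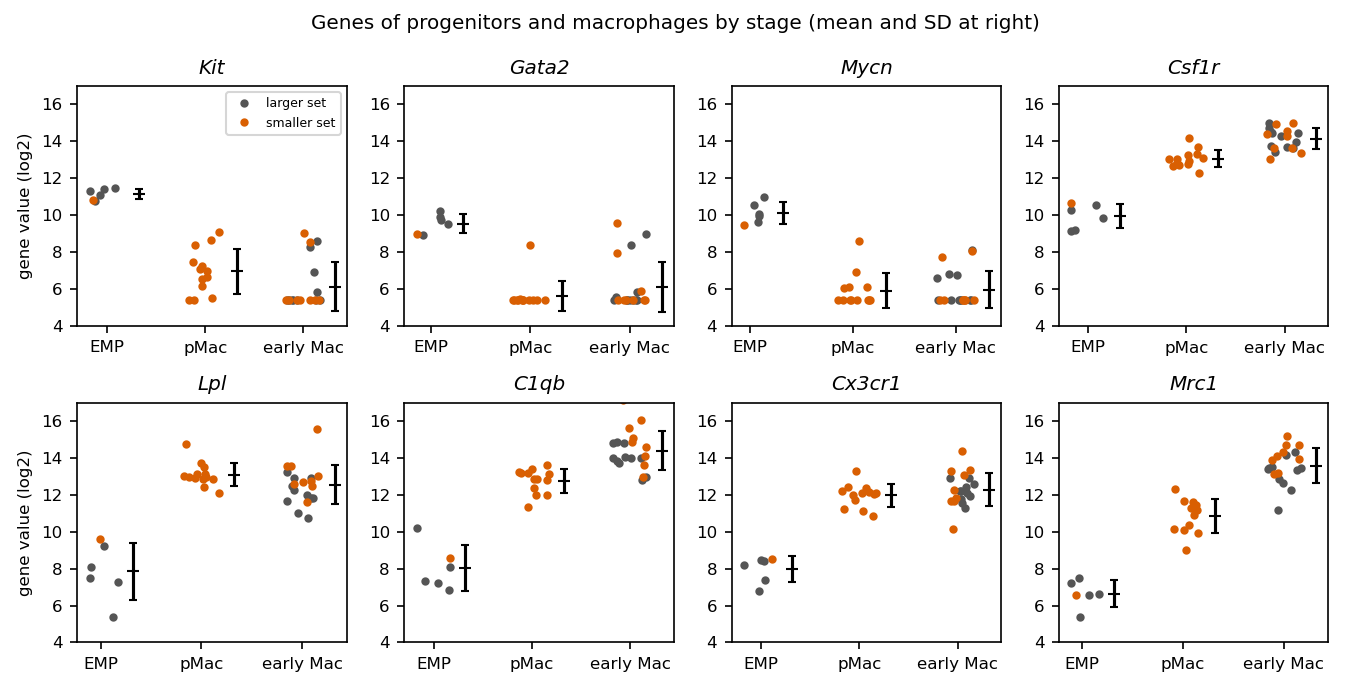
Level (log2) of 8 genes in each EMP (n = 6), pMac (n = 13) and early Mac (n = 20) library, coloured by inferred sample set, with the mean and SD at the right of each group. Mycn averaged 10.10 ± 0.59 in EMP and 5.91 ± 0.94 in pMac, and Lpl 7.84 ± 1.52 and 13.09 ± 0.65.

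The step from pMac to Mac of E10.25 and E10.5 was compared next. The hexokinase Hk3 rose by 4.89 ± 0.32, from 5.78 ± 0.74 in pMac (n = 13) to 10.80 ± 0.81 in early Mac (n = 20; adjusted p = 2.78e-16). The scavenger receptor Stab1 rose by 4.70 ± 0.36 and Slc40a1, the iron exporter ferroportin, by 4.18 ± 0.46. Abca1 (3.82) and Apoe (3.65), which export cholesterol, and Hmox1 (3.20) and Blvrb (3.12), which degrade heme, also rose. Flt1, a VEGF receptor, fell most, and decreased by 3.64 ± 0.43, and the cyclin Ccnd2 fell by 3.48 ± 0.44.

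Of the macrophage core list, 14 of 23 measured members (16 adjusted over the list alone) rose, among them Adgre1 (3.04), Mrc1 (2.72), Trem2 (2.70) and Mertk (2.40), with adjusted p = 5.38e-06 in the list test and adjusted p = 0.145 with an estimated correlation. Csf1r rose further by 1.07 ± 0.24, while Cx3cr1 differed by 0.39 ± 0.29 (adjusted p = 0.368). Of the Kupffer cell list, 8 of 13 measured members (9 adjusted over the list alone) rose, including Fcna (4.05), Id3 (2.07; adjusted p = 0.0015) and Timd4 (2.03), and 1 fell, with adjusted p = 0.145 with an estimated correlation. Iron and heme genes rose in 5 of 13 (5 adjusted over the list alone) and 1 fell (adjusted p = 0.183 with an estimated correlation). Erythroid genes rose in 10 of 16 (10 adjusted over the list alone), with the embryonic globins Hbb-y (4.64) and Hba-x (4.25) among the largest rises of all genes (adjusted p = 0.183 with an estimated correlation). The progenitor list fell in 3 of 12 (5 adjusted over the list alone), with Cd34 down by 2.36 ± 0.41 (adjusted p = 0.188 with an estimated correlation). Neutrophil granule genes fell in 3 of 5 (3 adjusted over the list alone), including the peroxidase Mpo (-2.54; adjusted p = 0.183 with an estimated correlation). Plac8 fell by 2.42 ± 0.41, the immediate early gene Egr1 by 2.10 ± 0.41 and H2-Ab1, an MHC class II gene, by 2.51 ± 0.70. Among pMac libraries of E9.5 the monocyte list ranged from 6.65 to 9.15 in caudal embryo and from 6.15 to 8.03 in brain. The fall of H2-Ab1 rests on pMac of E9.5: at E10.25 only, it fell by 0.37 (adjusted p = 0.823), and the related H2-Aa differed by 0.04. The MHC class II list ranged from 5.61 to 10.68 among pMac libraries of E9.5, and at E10.25 was at 6.61 in brain, 6.96 in limbs and 6.72 in liver pMac (n = 1 each), against means of 6.61, 6.71 and 6.31 in Mac of these tissues, and in yolk sac pMac (n = 1) below the Mac mean of 7.14.

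The count was 1827 genes, 917 higher and 910 lower in Mac. Within the smaller set (9 Mac and 13 pMac libraries) 497 genes passed, 387 higher and 110 lower, and with the set as a covariate 922. At E10.25 only, where 4 pMac libraries are left, the count was 136, and in yolk sac alone 50. Most pMac libraries are of E9.5 and all early Mac are of E10.25 or E10.5, so age and stage largely run together in this step.

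pMac of E9.5 were compared between brain (n = 4), caudal embryo (n = 3) and yolk sac (n = 2) to ask whether precursors of different sites already differ. No gene passed the limma F test over 10948 genes, and 146 had an unadjusted p under 0.05. With no filter 5 genes passed, and with replicate numbers as a block 3 did, so the result depends on these choices. Csf1r differed by 0.19 between the highest and lowest tissue and Cx3cr1 by 0.01, while Adgre1 differed by 3.30 and Cd74, the MHC class II chaperone, by 4.69, each with an adjusted p of 1. On simulated data 39 of 50 rises of 3, 35 of 50 falls of 3 and 2 of 50 rises of 1.5 were found in this design, so most smaller differences were not detectable.

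Early Mac of brain, limbs, liver and yolk sac were compared at E10.25 and E10.5, each tissue against the mean of the others, to find the earliest tissue differences. In brain Mac (n = 5), Sparc was higher by 3.54 ± 0.69 (adjusted p = 0.017) and Olfml3 by 2.99 ± 0.61, both members of the microglia list. The checkpoint receptor Havcr2 (3.07) and the protease inhibitor Spint1 (2.93) were also higher, and Msr1 had a log2 difference of -2.84 ± 0.61. Of the 20 fits that leave out 1 library, 17 ended the call of Msr1, 9 that of Olfml3 and 3 that of Sparc. The microglial factor Sall1 was at 6.53 ± 1.17 in brain at E10.25 (n = 3) and 7.48 ± 0.33 at E10.5 (n = 2), a difference of 1.14 ± 0.47 from the other tissues (adjusted p = 0.998). The microglia list was higher in 3 of 19 measured members (10 adjusted over the list alone), with a median difference of 1.40 and an adjusted p of 2.44e-05, and the call holds with an estimated correlation (adjusted p = 5.19e-05). Of the Kupffer cell list, 0 of 14 (8 adjusted over the list alone) were lower in brain, and the list passed its test (adjusted p = 3.49e-04). Liver, where this list was higher, is in the mean of the other tissues here.

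In early liver Mac (n = 4), the scavenger receptor gene Timd4 was at 11.02 ± 1.16 at E10.25 (n = 2), a difference of 3.32 ± 0.67 (adjusted p = 0.0522). The inhibitor of DNA binding Id3 differed by 2.48 ± 0.69 (adjusted p = 0.337), Id1 by 1.84 ± 0.57 (adjusted p = 0.415) and the liver X receptor gene Nr1h3 by 2.70 ± 0.77 (adjusted p = 0.369). Of the Kupffer cell list, 0 of 14 (8 adjusted over the list alone) were higher, with a median difference of 1.58 and an adjusted p of 3.17e-04 (6.28e-04 with an estimated correlation). The genes that passed were Id2 (2.46 ± 0.47), the von Willebrand factor gene Vwf (2.66 ± 0.43), Zrsr1 (3.20 ± 0.58) and the DNA sensor adaptor Tmem173 (-3.22 ± 0.57). In early limb Mac (n = 4) only Slc40a1 passed, at -3.33 ± 0.51 (adjusted p = 0.00271), and Slc40a1 was higher in yolk sac Mac (n = 7) by 2.15 ± 0.43. Yolk sac Mac were also higher in Hmox1 (1.81 ± 0.38), the complement receptor C5ar1 (2.15 ± 0.42) and the globin genes Hba-a2 (3.40 ± 0.60) and Hba-x (2.85 ± 0.60). Markers of other cells varied among the yolk sac Mac libraries of E10.5 (n = 3). The megakaryocyte list ranged from 5.64 to 10.16, the mast cell list from 5.38 to 9.30 and the fibroblast list from 5.38 to 8.97. The calls of Hmox1 and Hba-x ended in 14 of the 20 fits that leave out 1 library, that of Slc40a1 in 10, C5ar1 in 8 and Hba-a2 in 1, and in liver that of Id2 in 6, Zrsr1 in 3 and Tmem173 in 2. Their erythroid list was higher in 3 of 15 (12 adjusted over the list alone) and the iron and heme list in 2 of 13 (6 adjusted over the list alone), with adjusted p = 0.493 and 0.606 with an estimated correlation. The neural factor Sox11 had a difference of -3.12 ± 0.54. Id1, Id3 and several list members may have been chosen by the study on these samples, so their direction is not independent evidence here or at later ages.

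The counts were 13 genes in brain, 1 in limbs, 4 in liver and 18 in yolk sac of 11288 tested (20 libraries). Other splits of the libraries called up to 434 genes for brain, 4 for limbs, 3 for liver and 848 for yolk sac, and 12 of 100 splits matched the limb count, so chance cannot be excluded for limbs or, with a margin of 1 gene, for liver, and the libraries hold structure other than tissue. Within the larger set the counts by limma were 2 in brain and 0 in limbs, liver and yolk sac (962, 761 and 1314 at an unadjusted p under 0.05), and within the smaller set 4 in yolk sac and 0 in brain, limbs and liver (224, 367 and 689). Leaving out brain E10.5 replicate 1 gave 4 genes in brain and leaving out replicate 2 gave 7, while without limbs E10.5 replicate 2 or yolk sac E10.25 replicate 4 it was 8. For liver the count was 8 without liver E10.25 replicate 1 or yolk sac E10.5 replicate 3, 7 without brain E10.5 replicate 2, and 2 without either liver E10.5 library. For yolk sac the count moved with 18 of the 20 libraries: it was 1 without yolk sac E10.5 replicate 3, 2 without limbs E10.5 replicate 1, 3 without limbs E10.5 replicate 2, liver E10.25 replicate 1, liver E10.5 replicate 1, yolk sac E10.25 replicate 2 or yolk sac E10.5 replicate 2, and 4 without brain E10.25 replicate 1 or limbs E10.25 replicate 1. It was 5 without brain E10.25 replicate 2 or liver E10.5 replicate 2, 6 without yolk sac E10.5 replicate 1, 8 without yolk sac E10.25 replicate 3, 9 without brain E10.5 replicate 2 and 11 without limbs E10.25 replicate 2. Higher counts came without brain E10.25 replicate 3 (148), liver E10.25 replicate 2 (215) and yolk sac E10.25 replicate 4 (410). For limbs it was 2 without limbs E10.25 replicate 2, liver E10.25 replicate 2, liver E10.5 replicate 2 or yolk sac E10.5 replicate 1, and 3 without brain E10.25 replicate 2, limbs E10.25 replicate 1 or liver E10.25 replicate 1. It was 4 without limbs E10.5 replicate 1, 5 without liver E10.5 replicate 1 and 6 without limbs E10.5 replicate 2. With 1 value per group no gene passed in brain or liver (510 and 957 at an unadjusted p under 0.05).

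From E14.5 to P21, Mac of brain, kidney, liver, lung and skin were compared, each with the mean of the other tissues over 5 ages (48 libraries, 11788 genes). A list that is high in a single tissue raises this mean for each other tissue, and so tends to appear lower there. In brain (n = 10), Sall1 was at 13.11 ± 0.68 and at 5.73 ± 0.88 elsewhere, a difference of 7.38 ± 0.36 (adjusted p = 1.56e-22). The protease inhibitor Serpine2 was higher by 7.21 ± 0.41, the matrix gene Sparc by 6.99 ± 0.60 and the purinergic receptor P2ry12 by 5.21 ± 0.52. All 19 measured members of the microglia list were higher (19 adjusted over the list alone), with a median difference of 5.05, including Olfml3 (6.40), Siglech (6.36), Sall3 (5.25) and Tmem119 (4.21), and the call holds with an estimated correlation (adjusted p = 3.69e-08). Cx3cr1 (4.22) and Trem2 (4.09) were also higher. Neural cell markers were higher in 5 of 8 (6 adjusted over the list alone), among them the neuronal tubulin Tubb3 (3.57) and the glial transporter Slc1a3 (3.27).

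The Kupffer cell list was lower in brain in 15 of 19 measured members (18 adjusted over the list alone), such as Marco (-3.69), Clec4f (-3.24), Spic (-3.05) and Timd4 (-2.86), and this call holds with an estimated correlation (adjusted p = 1.98e-04). Liver is in the mean of the other tissues, so this is in part the high level of the list in liver. At P21 the list averaged 6.07 in brain, 6.79 in skin, 6.91 in lung (n = 1) and 7.60 in kidney. At E18.5 it averaged 6.27 in brain and 6.05 in skin. The largest negative differences were those of the complement gene Cfp (-5.18 ± 0.42), the lectin Clec4n (-4.84) and the fatty acid receptor Cd36 (-4.77). Interferon response genes were lower in 7 of 18 (9 adjusted over the list alone) and iron and heme genes in 6 of 15 (8 adjusted over the list alone), with adjusted p = 0.0355 and 0.0355 with an estimated correlation. The count was 1013 genes, 687 higher and 326 lower, and 641 within the larger set, while the smaller set holds too few libraries for these comparisons.

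In liver (n = 9), the Kupffer cell lectin Clec4f was at 15.40 ± 2.43 and at 6.19 ± 1.32 elsewhere, a difference of 9.04 ± 0.57 (adjusted p = 1.02e-17). Cd5l was higher by 8.87 ± 0.63, the scavenger receptor Marco by 7.82 ± 0.57, the complement receptor Vsig4 by 7.27 ± 0.53 and Timd4 by 6.13 ± 0.59. All 19 measured members of the Kupffer cell list were higher (19 adjusted over the list alone), with a median difference of 6.01, including the transcription factor genes Id3 (6.09), Nr1h3 (5.60), Spic (5.14) and Id1 (4.01), and the call holds with an estimated correlation (adjusted p = 2.49e-08). Iron and heme genes were higher in 11 of 15 (11 adjusted over the list alone), with Slc40a1 at 4.74 and Hmox1 at 3.60, and lipid genes in 6 of 15 (8 adjusted over the list alone), with Pltp at 4.61 and Apoc1 at 4.59. Interferon response genes were higher in 7 of 18 (12 adjusted over the list alone), among them Rsad2 (4.16) and Irf7 (3.83). These calls hold with an estimated correlation (adjusted p = 9.04e-04, 0.0073 and 0.0278).

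Markers of other liver cells moved with these genes. Hepatocyte genes were higher in 10 of 10 (10 adjusted over the list alone), led by albumin, Alb (6.93 ± 0.56), and the apolipoprotein Apoa1 (6.14), and erythroid genes in 13 of 15 (15 adjusted over the list alone), led by Hbb-bs (6.97 ± 0.99). The adjusted p with an estimated correlation was 1.87e-05 for hepatocyte and 9.07e-04 for erythroid genes. Endothelium genes were higher in 3 of 5 (3 adjusted over the list alone) (adjusted p = 0.0291 with an estimated correlation) and T and NK cell genes in 2 of 3 (2 adjusted over the list alone) (adjusted p = 0.284 with an estimated correlation). Lists of other blood cells were high in single libraries: of the 2 liver libraries of P2, replicate 2 had the B cell list at 10.34, T and NK cell at 8.94, neutrophil at 10.18, mast cell at 9.31 and MHC class II at 12.30, against 7.46, 6.49, 5.88, 5.55 and 8.59 in replicate 1. The microglia list was lower in liver in 11 of 19 (11 adjusted over the list alone), with Fcrls at -5.38 and Siglech at -4.02, and Cx3cr1 had a difference of -3.34 ± 0.67. Brain, where these genes are high, is in the mean of the other tissues here. Also lower were Spp1 (-4.74), the transporter Slco2b1 (-4.68) and the chemokine receptor Ccr1 (-3.75). The count was 1037 genes, 581 higher and 456 lower. Of the 9 liver libraries 4 held under 18000 transcripts above the floor, and without all libraries of that kind 696 genes passed.

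**Figure D2:**
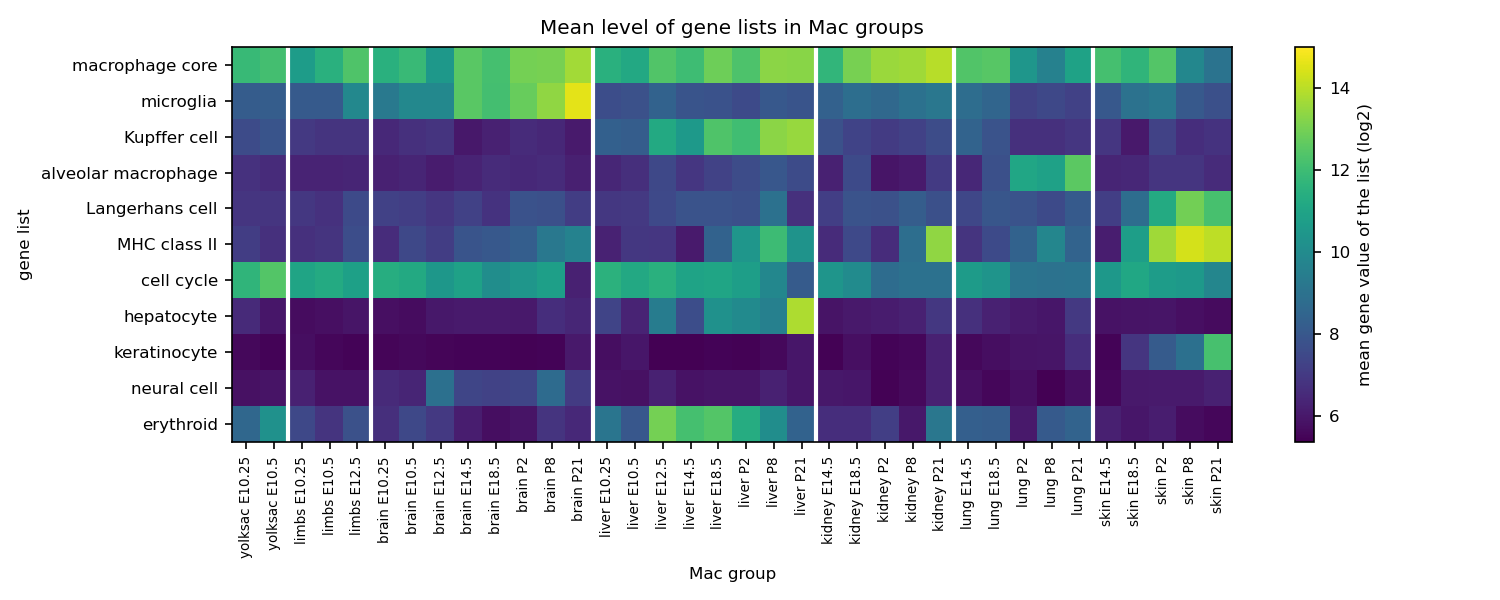
Mean level (log2) of the members of each fixed gene list in every Mac group, shown as colour, with groups ordered by tissue and age. The levels show the microglia list in brain and the Kupffer cell list in liver, whose median differences from other tissues after E14.5 were 5.05 and 6.01.

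In skin (n = 11), genes of Langerhans cells, the macrophages of the epidermis, were higher. The adhesion gene Epcam was higher by 5.53 ± 0.54 (adjusted p = 2.69e-10), the junction gene Cldn1 by 4.97 ± 0.55, E-cadherin (Cdh1) by 4.87 ± 0.59, langerin (Cd207) by 4.34 ± 0.72 and the factor Runx3 by 4.17 ± 0.51. The Langerhans cell list was higher in 9 of 14 measured members (11 adjusted over the list alone), with the aryl hydrocarbon receptor Ahr at 2.80. MHC class II genes were higher in 8 of 11 (9 adjusted over the list alone), including H2-Aa (5.42), H2-Ab1 (5.36) and Cd74 (4.90). Both calls hold with an estimated correlation (adjusted p = 0.00475 and 0.0245). Keratinocyte genes were higher in 8 of 8 (8 adjusted over the list alone), with Krt14 at 4.10. Immediate early and stress genes were higher in 3 of 13 (6 adjusted over the list alone), with Fos at 2.49 and Egr1 at 2.38 (adjusted p = 0.0646 with an estimated correlation). Of the 48 fits that leave out 1 library, 5 ended the call of Egr1 and 3 that of Fos.

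The macrophage core list was lower in skin in 12 of 24 (16 adjusted over the list alone), among them the engulfment receptor Mertk (-4.42 ± 0.46), Fcgr1 (-2.75) and Mrc1 (-2.34). This list averaged 12.15 at E14.5, 11.69 at E18.5 and 12.43 at P2 in skin, and was low only at P8 (9.83) and P21 (9.05). These ages had the highest mean levels of the keratinocyte list (8.93 and 12.20) and of the Langerhans cell list (12.94 and 12.21). Keratinocyte levels of single libraries at P2 (6.76 to 9.24) overlapped those at P8 (8.55 to 9.31). What lowers the macrophage core list at these ages was not tested. Phagocytic and complement receptors were lower in 9 of 17 (11 adjusted over the list alone), and the Kupffer cell list in 12 of 19 (14 adjusted over the list alone), with Slc40a1 at -3.73. The mean of the other tissues includes liver, where the Kupffer cell list is high. Erythroid genes were lower in 8 of 15 (11 adjusted over the list alone), with Hba-a2 at -4.39, a gene whose reads cannot be separated with certainty from those of Hba-a1. The calls hold with an estimated correlation (adjusted p from 0.00475 to 0.0337). The count was 937 genes, 587 higher and 350 lower, and 409 within the larger set. It was 611 without skin P21 replicate 1 and 622 without skin P8 replicate 2.

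In kidney (n = 10), the membrane gene Ms4a14 was higher by 5.46 ± 0.67 (adjusted p = 8.79e-07). Stab1 was higher by 4.21 ± 0.76, the C-type lectin receptor gene Cd93 by 3.90 ± 0.60, the lectin Clec10a by 3.57 ± 0.77 and Cx3cr1 by 2.75 ± 0.64. The macrophage core list was higher in 5 of 24 (7 adjusted over the list alone), with Mrc1 (2.72) and Maf (2.25) among the members that passed. At E14.5 this list averaged 11.71 in kidney, below brain (12.52), lung (12.38) and skin (12.15). From E18.5 on it was above brain, at 13.95 against 13.65 at P21. Lung (10.93, n = 1) and skin (9.05) were low at P21, and both are in the mean of the other tissues. Of the phagocytic and complement receptors, 5 of 17 (7 adjusted over the list alone) were higher, including C3ar1 (2.73), and 2 were lower. The Kupffer cell list, which is high in liver and so in the mean of the other tissues, was lower in 5 of 19 (10 adjusted over the list alone), with Marco at -2.61 and Clec4f at -2.47. None of these list calls holds with an estimated correlation (adjusted p = 0.282 for each). The serine synthesis enzyme Phgdh (-3.23 ± 0.73) and the kinase Sgk1 (-2.90 ± 0.78) were lower, although 5 of the 48 fits that leave out 1 library ended the call of Sgk1 and 1 that of Maf, and no gene of the kidney epithelium list was detected in enough libraries to be tested. The 4 measured genes of that list averaged 7.27 at P8 and 10.59 at P21 (8.84 and 12.34 in the 2 libraries), against 5.38 to 6.06 from E14.5 to P2. The P21 kidney libraries thus hold markers of epithelium. The endothelium list was at 5.62 and 10.27 in the P21 libraries. Whether RNA of such cells adds to the genes called higher in kidney, such as Stab1 and Cd93, was not tested. The count was 359 genes, 236 higher and 123 lower, and 206 within the larger set. Both kidney P2 libraries held under 18000 transcripts, and without all such libraries 197 genes passed. The count was 211 without P2 replicate 1, 206 without P2 replicate 2, 227 without P8 replicate 1, 233 without P8 replicate 2, and 15 with 1 value per group.

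In lung (n = 8), genes of alveolar macrophages were higher. Plet1 was higher by 4.26 ± 0.62, the carbonic anhydrase Car4 by 4.24 ± 0.67, the amino acid transporter Slc7a2 by 3.91 ± 0.55 and Pparg, a factor of alveolar macrophage development, by 2.98 ± 0.67 (adjusted p = 0.00743), at 9.35 ± 2.35 in lung and 6.36 ± 1.74 elsewhere. The alveolar macrophage list was higher in 8 of 15 measured members (13 adjusted over the list alone), with a median difference of 2.17, and the call holds with an estimated correlation (adjusted p = 0.0022). Fibronectin, Fn1 (4.45 ± 0.92), Cebpb (2.63) and Bhlhe40 (2.50) were higher, and Siglecf differed by 1.97 ± 0.61 (adjusted p = 0.0604). The macrophage core list was lower in 9 of 24 (12 adjusted over the list alone) and higher in 1, with C1qb (-3.12), Adgre1 (-2.18) and Csf1r (-1.91) among the lower members (adjusted p = 0.988 with an estimated correlation). In lung this list averaged 12.38 at E14.5 and 12.51 at E18.5, near the 12.52 and 12.18 of brain, and was lower from P2 on (10.44, 9.62 at P8 and 10.93 at P21). Both lung P2 libraries were low (10.30 and 10.59), of which only replicate 2 held under 18000 transcripts, whereas the libraries of kidney P2 and liver P21, all under 18000, had this list at 12.77 to 14.35 and 13.04 to 13.53. The microglia list, which is high in brain and so in the mean of the other tissues, was lower in 7 of 19 (13 adjusted over the list alone), with Tmem119 at -2.98 (adjusted p = 0.0648 with an estimated correlation). Of the 48 fits that leave out 1 library, 4 ended the call of Tmem119, 3 that of C1qb and 2 each those of Pparg, Bhlhe40 and Adgre1, and without all libraries of few detected transcripts none of these calls was left.

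The lung count was 335 genes, 109 higher and 226 lower. Of the 8 lung libraries 3 held under 18000 transcripts, among them the only libraries of P8 and P21, and without all such libraries no gene passed by limma (849 at an unadjusted p under 0.05). The count was 79 without P21 replicate 2, 88 without P8 replicate 2, 126 without P2 replicate 2, 167 without P2 replicate 1 and 508 without E14.5 replicate 1.

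**Figure D3:**
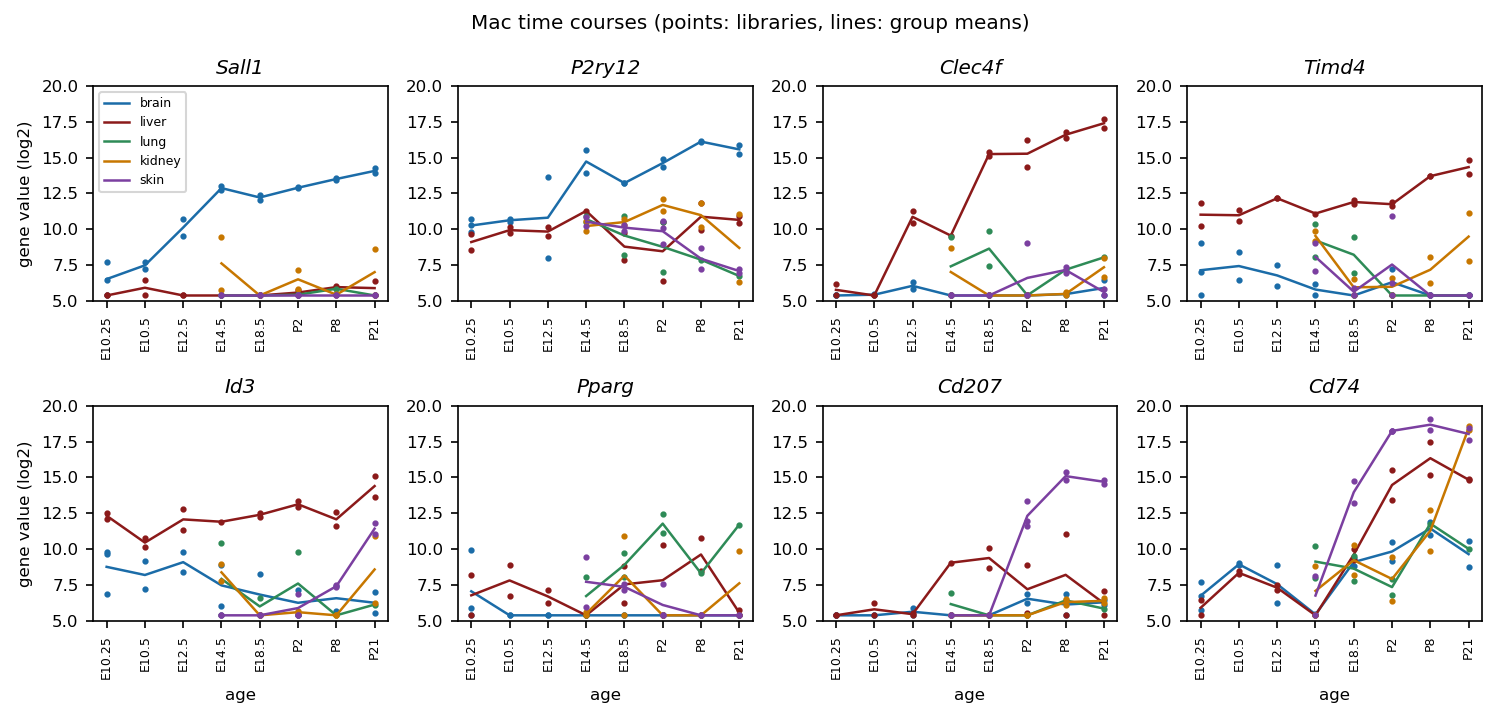
Level (log2) of 8 genes against age in brain, liver, lung, kidney and skin Mac, where points are libraries and lines join group means. Sall1 reached 14.07 in brain at P21, Clec4f 17.40 in liver and Cd207 14.70 in skin.

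Single genes took different courses within these tissues. Sall1 in brain was at 6.53 ± 1.17 at E10.25, 10.13 ± 0.86 at E12.5, 12.88 ± 0.23 at E14.5 and 14.07 ± 0.25 at P21. Clec4f in liver was near the floor at E10.25 (5.77 ± 0.56), at 10.87 ± 0.58 at E12.5 and at 15.25 ± 0.20 at E18.5, whereas Id3 was already at 12.33 ± 0.29 at E10.25. Spic, a factor of iron-recycling macrophages, was at 5.40 ± 0.02 in liver at E10.5 and 11.84 ± 1.61 at E12.5. In skin, Runx3 was at 6.45 ± 0.03 at E14.5 and 11.50 ± 0.27 at E18.5, before Cd207, which was at the floor of 5.38 at E18.5 and at 12.33 ± 0.94 at P2 (n = 3). Pparg in lung was at 6.73 ± 1.91 at E14.5 and 11.78 ± 0.94 at P2. The 2 brain libraries of E12.5 lay apart in the macrophage core list (8.96 and 12.04). Each mean is of 2 or 3 libraries, and the differences between neighbouring ages were not tested.

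The change with age, averaged over these 5 tissues, was measured as P21 (n = 9) minus E14.5 (n = 9). MHC class II genes had the largest rises, with H2-Eb1 up by 7.71 ± 1.05 (adjusted p = 9.43e-06), from the floor of 5.38 in all E14.5 libraries to 13.35 ± 3.80, and Cd74 up by 7.45 ± 1.08. The secreted gene Sparc rose by 3.51 ± 0.80, the myeloid factor Cebpa by 3.09 ± 0.65 and Spi1 by 1.96 ± 0.38. The endothelin receptor Ednrb fell most, and decreased by 5.15 ± 0.82, and F13a1 fell by 4.93 ± 0.97, the hyaluronan receptor Lyve1 by 4.36 ± 0.98, Stab1 fell by 3.39 ± 1.01 and Mrc1 by 2.93 ± 0.79. The MHC class II list rose in 8 of 11 measured members (9 adjusted over the list alone), which holds with an estimated correlation (adjusted p = 0.0285). Cell cycle genes fell in 13 of 25 (21 adjusted over the list alone), among them Bub1 (-4.20), Mcm4 (-3.74) and Ccnb1 (-3.59), with adjusted p = 7.4e-05 and adjusted p = 0.0697 with an estimated correlation. Keratinocyte genes rose in 4 of 8 (7 adjusted over the list alone), with Krt14 up by 4.18 ± 0.76 (adjusted p = 0.0697 with an estimated correlation), and Alb rose by 2.60 ± 0.71, genes with low levels in P21 libraries of several tissues. Of the 48 fits that leave out 1 library, 6 ended the call of Stab1 (without either E14.5 library of lung or skin, lung P21 replicate 2 or skin P21 replicate 2) and 1 each those of Mrc1 and Alb. The count was 801 genes, 332 higher and 469 lower. After centring on genes detected in most libraries most called genes were higher instead, and after centring on those detected in all most were lower, so this balance rests on the scaling. The size of the change varied by tissue, which was not tested: from E14.5 to P21 the mean level of the MHC class II list went from 6.15 to 14.05 in skin, 6.55 to 13.41 in kidney and 6.08 to 10.33 in liver, but from 7.88 to 9.63 in brain and 6.84 to 8.45 in lung, where it was 9.81 at P8 (n = 1). The cell cycle list went from 10.87 to 6.27 in brain and from 10.51 to 9.79 in skin. The smaller set holds no E14.5 library.

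Brain and liver were sampled at all 8 Mac ages, and P21 (n = 2 in each) was compared with E10.25 (n = 3 in brain, n = 2 in liver). In brain, Sall1 rose by 7.55 ± 0.81 (adjusted p = 4.26e-06), Tmem119 by 7.67 ± 1.60, P2ry12 by 5.31 ± 1.14 and Csf1r by 3.69 ± 0.70. The microglia list rose in 17 of 19 (18 adjusted over the list alone), and the call holds with an estimated correlation (adjusted p = 0.0231). Cell cycle genes fell in 21 of 25 (23 adjusted over the list alone), led by Top2a (-7.31 ± 0.75) and Mki67 (-7.16 ± 0.64), with adjusted p = 0.0231 with an estimated correlation, and Mrc1 fell by 7.12 ± 0.73. The macrophage core list rose in 13 of 24 (15 adjusted over the list alone) and fell in 1, and MHC class II genes rose in 5 of 11 (5 adjusted over the list alone) (adjusted p = 0.423 with an estimated correlation for each). The myelin gene Mbp rose by 6.85 ± 1.37, but its transcript with the highest mean fell by 0.56. The count was 1306 genes, 755 higher and 551 lower. It was 226 within the larger set, where 1 library of P21 and 2 of E10.25 are left, 632 without brain E10.25 replicate 3 and 642 without brain P21 replicate 2.

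In liver, Clec4f rose by 11.63 ± 0.83 (adjusted p = 5.96e-09), Marco by 10.65 ± 0.80, Cd5l by 10.62 ± 0.97, Vsig4 by 9.25 ± 0.89, and Cd74 by 8.94 ± 1.01. Timd4 rose by 3.32 ± 1.03, a call that ended in 13 of the 32 fits that leave out 1 library, and those of Hba-x, Hbb-y and Cx3cr1 below ended in 1 each. Id3 differed by 2.07 ± 1.18 (adjusted p = 0.295), Id1 by -0.10 ± 0.89 and Nr1h3 by 2.81 ± 1.16 (adjusted p = 0.131), genes that were already high at E10.25. On simulated data this contrast recovered 8% of rises of 3, so the missing calls of Id3 and Nr1h3 do not show that they stayed level. The Kupffer cell list rose in 13 of 20 (16 adjusted over the list alone) and hepatocyte genes rose in 11 of 13 (12 adjusted over the list alone), among them Ahsg (10.05), and both calls hold with an estimated correlation (adjusted p = 1.22e-05 and 0.0141). MHC class II genes rose in 6 of 11 (7 adjusted over the list alone) and cell cycle genes fell in 13 of 25 (15 adjusted over the list alone), with adjusted p = 0.0945 and 0.124 with an estimated correlation. The embryonic globins Hba-x and Hbb-y fell by 6.85 and 6.33, while Hbb-bs, an adult globin, rose by 7.89 ± 1.58. Ednrb fell by 7.27 ± 1.36 and Cx3cr1 by 4.87. The count was 1233 genes, 401 higher and 832 lower, 973 within the larger set, 616 without liver E10.25 replicate 1 and 369 without replicate 2. The balance of directions rests on the scaling. After centring on genes detected in most libraries most called genes were higher, and after centring on those detected in all most were lower. Both liver P21 libraries held under 18000 transcripts.

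The change differed between brain and liver for 752 genes (13647 tested), 538 with a higher change in brain. That balance rests on the scaling: after centring on genes detected in most libraries, most called genes had a lower change in brain. After centring on those detected in all, most had a higher change, as in the main fit. On simulated data 0 of 50 rises of 3, 1 of 50 falls of 3 and 9 of 50 rises of 5 were found in this contrast. Microglia genes had a higher change in brain in 9 of 19 (15 adjusted over the list alone), with Fcrls at 8.60 ± 1.38 and Trem2 at 8.65 ± 1.32 (adjusted p = 0.0735 with an estimated correlation). Kupffer cell genes had a lower change in brain in 11 of 20 (14 adjusted over the list alone), led by Clec4f (-11.10 ± 1.13), and the call holds with an estimated correlation (adjusted p = 2.12e-05). Hepatocyte genes had a lower change in 8 of 13 (11 adjusted over the list alone), with adjusted p = 0.0514 with an estimated correlation. The interferon factor Irf7 (-8.67 ± 2.05) and the cell cycle genes Top2a (-6.89 ± 1.11) and Mki67 (-5.63 ± 0.95) also had a lower change in brain, and the call of Irf7 ended in 1 of the 32 fits that leave out 1 library. The count was 235 within the larger set, where 1 brain library of P21 is left, 425 without liver E10.25 replicate 1 and 383 without replicate 2. With only the 4 groups compared, the counts were 608 in brain, 443 in liver and 188 for the difference.

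**Figure D4:**
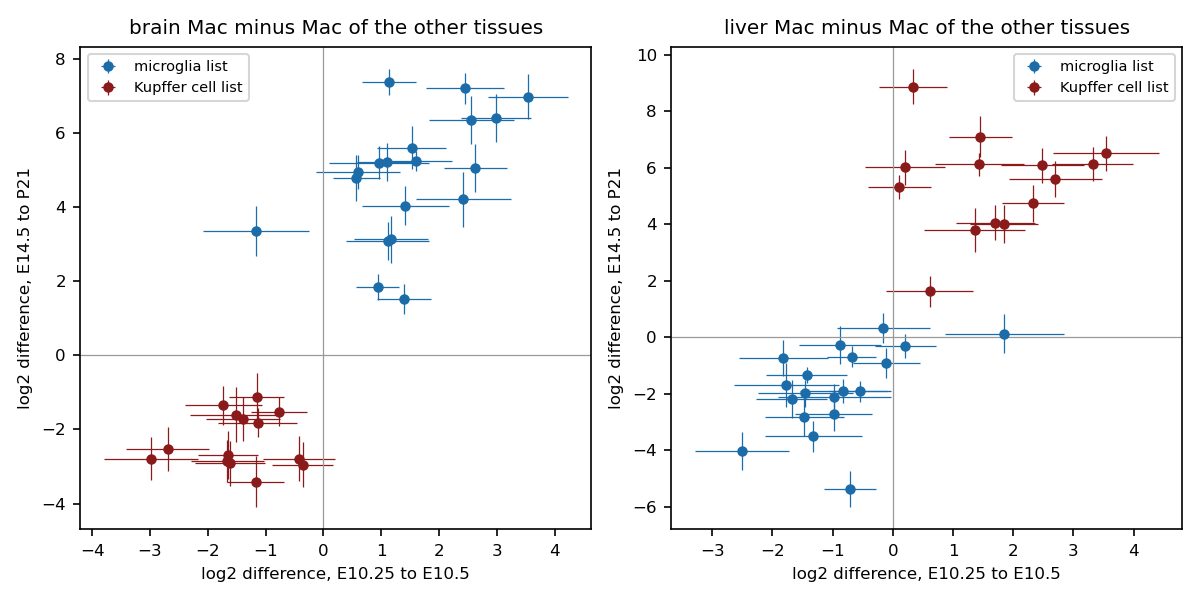
Log2 difference of each microglia and Kupffer cell list gene from the other tissues at E10.25 to E10.5 (horizontal axis) and at E14.5 to P21 (vertical axis), in brain and liver Mac, with bars of 1 standard error. Sparc in brain lies at 3.54 and 6.99, and Timd4 in liver at 3.32 and 6.13.

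Early and late tissue differences were then compared over 10874 genes tested at both stages, where the tissues in the reference mean differ. Of the 11 genes higher in early brain Mac, 10 were higher in late brain Mac (588 genes), against 0.595 by chance, among them Eml5, Gal3st4, Havcr2, Olfml3, Pmepa1, Rtn4rl1, Sparc, Spint1 and Spsb1. Msr1, the 1 gene lower in early brain Mac, was also lower late, against 0.0257 by chance, but 17 of 20 fits that leave out 1 library ended its early call. Of the 3 genes higher in early liver Mac, Id2 was higher late (0.127 by chance), and the gene lower early, Tmem173, was not lower late. The brain overlap was 11 genes in all, 4 without brain E10.5 replicate 1, and 7 without brain E10.5 replicate 2, limbs E10.25 replicate 1, limbs E10.5 replicate 2, liver E10.25 replicate 2 or yolk sac E10.25 replicate 4. The liver overlap of 1 gene was 0 without limbs E10.25 replicate 1, limbs E10.5 replicate 1, liver E10.25 replicate 2 or either liver E10.5 library, and 4 without brain E10.5 replicate 2. It was 3 without liver E10.25 replicate 1 or yolk sac E10.5 replicate 3, and 2 without brain E10.25 replicate 3, limbs E10.25 replicate 2, limbs E10.5 replicate 2, yolk sac E10.25 replicate 3, either kidney P2 library, lung P8 replicate 2 or lung P21 replicate 2. The brain overlap was 2 with the values as deposited and 0 with 1 value per group or within the larger set, where 1 gene was called higher in early brain.

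**Figure D5:**
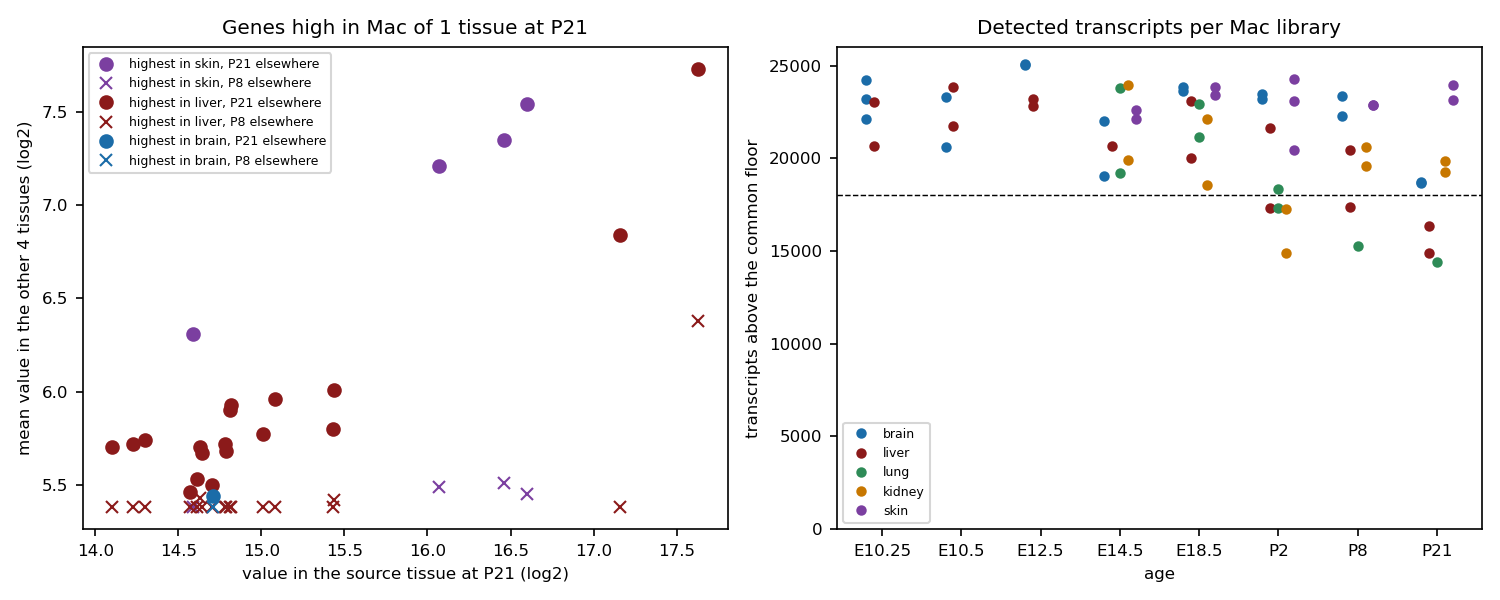
The left panel plots the P21 level (log2) of genes at 14 or more in 1 tissue and near the floor elsewhere at P2 against their mean in the other 4 tissues at P21 and at P8, and the right panel the transcripts above the floor in each brain, liver, lung, kidney and skin Mac library, with a dashed line at 18000. Krt14, at 16.60 in skin at P21, averaged 7.54 in the other tissues at P21 and 5.45 at P8.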

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

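The tests in this part were planned before the data were examined. For the groups of 4 libraries, brain pMac of E9.5 and yolk sac Mac of E10.25, 47 series of values (marker gene levels and transcripts detected) were tested for a library far from the others with Dixon's criterion, and 6 exceeded it. The criterion marks about 1 in 20 groups by chance where values vary freely, but that rate does not hold where the other libraries lie at the floor, since a single detected value then exceeds it. In brain pMac of E9.5, Sall1 was at 6.17 in replicate 1, with the others at the floor of 5.38, and Spic was at 7.62 in replicate 3, with the others at 5.50 or lower. In yolk sac Mac of E10.25, replicate 1 stood apart with Siglecf at 8.85 and Spic at 5.90, replicate 3 with Ahr at 7.48 and replicate 2 with Runx3 at 9.07. In these 6 cases all other libraries of the group were at or near the floor, at 5.98 or lower.

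The change from E10.25 to P21 differed between brain and liver Mac for 752 genes by the interaction contrast of the limma fit. Among the genes with the largest calls, the brain change exceeded the liver change for the transcription factor Mlxipl by 11.37, the adhesion receptor Adgrg1 by 9.88, the myelin gene Mbp by 9.55, the lysosomal enzyme Idua by 9.42 and Pank4 by 9.26. In the other direction, the difference was -11.10 for Clec4f, -10.84 for Cd5l, -10.38 for the complement factor Cfb, -10.28 for the hepatic enzyme Cyp2e1 and -10.05 for the plasma protein gene Ahsg. Of the marker genes fixed beforehand, Cx3cr1 had a difference of 8.73, Sall1 7.04, Sall3 4.75, Mrc1 -7.66, Timd4 -5.09 and the MHC class II gene Cd74 -6.03. Of the 32 fits that leave out 1 library, 6 ended the call of Timd4, 2 that of Cd74 and 1 that of Sall3. Cyp2e1 and Ahsg are hepatocyte genes, and both liver P21 libraries had few detected transcripts. The value for Mbp rests on transcripts other than the 1 with the highest mean.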

How the results depend on the processing

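The tests here of deposited values without the floor, single or equal numbers of transcripts, centring, sample sets and libraries with few detected transcripts were chosen only after the data were seen, and the others were fixed before the data were examined. Of 35851 tests of 675 pairs of a named gene and a comparison over all alternatives, 33191 kept their direction and side of the threshold, 2655 kept the direction and lost the call, and 5 turned. These are H2-Aa (0.03) and Slc1a3 (0.09) with replicate numbers as a block and H2-Aa at E10.25 only (0.04) for early Mac against pMac, Flt3 in the smaller set, with 1 EMP library, for pMac against EMP (0.37), and Mbp with only the transcript of the highest mean for brain P21 against E10.25 (-0.56). The cause was not tested. Not run were size factors or tests that need counts and a pseudocount of 0.1, since the values are log2, and 1 value per group for pMac of E9.5 and the time course, where no spread would be left. Sets without libraries on both sides of a comparison were not fitted. Of the 35851 tests, 27856 left out 1 library and so shared nearly all libraries with the main fit, and 26483 of these kept the call. Fewer kept it in the smaller set (51 of 216), in yolk sac only (44 of 131) and with 1 value per group (344 of 504).

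The main counts were 646 (pMac against EMP), 1827 (early Mac against pMac), 1013, 359, 1037, 335 and 937 (late brain, kidney, liver, lung and skin), 801 (P21 against E14.5), 13, 1, 4 and 18 (early brain, limbs, liver and yolk sac), 0 (pMac between tissues by limma, 146 at an unadjusted p under 0.05), 1306, 1233 and 752 (P21 against E10.25 in brain, in liver and their difference), and overlaps of 11 (brain) and 1 (liver). Values are given below where they moved by over 1.5 times or a call ended, and for these the cause was not tested. With no filter, early limbs gave 16, early liver 15, yolk sac 1, pMac between tissues 5 and the liver overlap 4. With 1 value per group, late brain and liver gave 537 each, kidney 15, skin 372, P21 against E14.5 256, yolk sac 2, and early brain, early liver and both overlaps 0 (510 and 957 genes in early brain and liver at an unadjusted p under 0.05). At E10.25 only the stage counts were 339 and 136, and in yolk sac only 69 and 50. With 1 mean per tissue and time, kidney gave 928, lung 1264, P21 against E14.5 1291, yolk sac 81 and the liver overlap 2. With only the 4 groups of the time course the counts were 608, 443 and 188. Of the list tests, 136 were called by fry and 46 by camera with an estimated correlation, which tests a list against the other genes. Both stage counts without the tissue covariate, and both overlaps without a minimum difference, stayed within 1.5 times.

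Values as deposited gave early brain 3, limbs 2, liver 2, the brain and liver difference 449 and the brain overlap 2. The transcript with the highest mean gave yolk sac 37 and the liver overlap 4, and equal numbers of transcripts early brain 6, yolk sac 33 and the brain overlap 5. With the set as a covariate the stage counts were 177 and 922 and the liver overlap 2. The smaller set alone gave 8 and 497 between stages, 4 in yolk sac, and by limma 0 in early brain, limbs and liver and in brain P21 against E10.25 (224, 367, 689 and 4310 at an unadjusted p under 0.05), the last with 1 library on each side, taken to vary like the others. The larger set alone gave late brain 641, kidney 206, skin 409, early brain 2, brain P21 (1 library) against E10.25 226, the brain and liver difference 235, and by limma 0 in early limbs, liver and yolk sac (962, 761 and 1314 at an unadjusted p under 0.05) and 0 in both overlaps. Without libraries of few detected transcripts, kidney gave 197, lung 0 by limma (849 at an unadjusted p under 0.05) and brain P21 against E10.25 2034.

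Centring on genes detected in most libraries gave P21 against E14.5 1221, early limbs 4, early liver 11, liver P21 against E10.25 2240, the brain and liver difference 1161 and the liver overlap 6, and centring on those detected in all gave early limbs 9, early liver 11 and the liver overlap 6. It moved the share of called genes that were higher, with no named gene turning. From the main share to the first and second centring, it was 65.8% to 48.9% and 27.8% for pMac against EMP, 67.8% to 48.9% and 67.5% for late brain, 65.7% to 52.2% and 53.6% for kidney, 56.0% to 66.7% and 37.1% for liver, 32.5% to 77.6% and 40.5% for lung, 62.6% to 59.1% and 83.8% for skin, and 41.4% to 78.0% and 24.4% for P21 against E14.5. Of early limb genes 0 of 1 was higher, and 3 of 4 and 8 of 9 with centring. It was 66.7% to 26.9% and 17.4% for yolk sac, 57.8% to 46.7% and 44.7% for brain P21, 32.5% to 88.4% and 24.1% for liver P21, and 71.5% to 14.2% and 71.1% for their difference. Shares of higher against lower genes therefore rest on the scaling. The median log2 difference of all genes moved with the first centring from 0.126 to -0.152 for pMac against EMP, 0.179 to -0.137 for late brain, -0.369 to 0.061 for lung, -0.170 to 0.318 for P21 against E14.5, -0.270 to 1.168 for liver P21 and 0.254 to -1.329 for the difference of brain and liver, and with the second from 0.221 to 0.471 for skin and -0.101 to -0.313 for late liver.

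Replicate numbers do not pair most libraries: of 126 same-numbered pairs 16 had a correlation over 0.1 after group means were removed (median 0.0186, -0.149 to 0.245). Where both groups hold 2 libraries, both numbers give the same value, so the pairs are not independent. Brain and caudal pMac of E9.5 were at 0.204, 0.229 and 0.173, so pairing is not excluded there. With the replicate number as a block, the counts were 402 and 631 between stages, 162 in lung, 18 in early liver, 3 for pMac between tissues, 364 for the brain and liver difference and 8 for the liver overlap.

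Leaving out each library in turn gave 487 to 758 (pMac against EMP), 1618 to 2126 (early Mac against pMac), 792 to 1071, 206 to 474, 850 to 1128, 79 to 508 and 611 to 1038 (late brain, kidney, liver, lung, skin), 559 to 909 (P21 against E14.5), 4 to 15, 1 to 6, 2 to 8 and 1 to 410 (early brain, limbs, liver, yolk sac), 0 (pMac between tissues), 632 to 1567, 369 to 1482 and 383 to 1016 (brain P21, liver P21, difference), and 4 to 11 and 0 to 4 (brain and liver overlap).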

Other observations

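Mac of E12.5 entered no tissue comparison except the brain and liver time course, and their values are given here as chosen after they were seen. In limb Mac of E12.5 (n = 2), Stab1 was at 16.90 ± 0.15, Csf1r at 15.59 ± 0.26, Mrc1 at 14.63 ± 0.77, Cx3cr1 at 14.14 ± 0.84 and Mki67, a gene of dividing cells, at 14.17 ± 1.13, while Kit and Ccr2 were at the floor. P2ry12 was at 11.29 ± 0.70 in limbs, 10.81 ± 4.01 in brain and 9.84 ± 0.48 in liver at this age. The mean level of the Kupffer cell list was 11.21 in liver (n = 2) and 6.83 in limbs and brain. Of the 2 brain libraries of E12.5, the microglia list was at 8.02 in 1 and 11.70 in the other. The macrophage core list (8.96 and 12.04), cytokine and chemokine receptors (7.34 and 10.26) and phagocytic and complement receptors (7.31 and 9.73) lay apart as well, so the gap is not one of microglia genes alone, and the neural cell list averaged 8.93, the highest of the brain groups, with Tubb3 at 12.18 ± 0.61.

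MHC class II genes rose at different ages in different tissues, a comparison of levels that was not tested. In skin the list averaged 6.15 at E14.5, 10.77 at E18.5 and 13.62 at P2, and in kidney 8.87 at P8 and 13.41 at P21, while in lung it was 8.39 at P2, 9.81 at P8 (n = 1) and 8.45 at P21 (n = 1), and in brain 9.63 at P21. In liver the 2 libraries lay apart at P2 (8.59 and 12.30) and P8 (13.67 and 10.26), and at P21 the list averaged 10.33. Cell cycle genes averaged 10.80 in brain at P8 and 6.27 at P21, and 9.79 in skin at P21. Of the 2 liver libraries of P8, 1 had the B cell list at 12.09 and the T and NK cell list at 10.44, against 7.76 and 6.26 in the other, and the dendritic cell list at 10.27. At P2 the same lists were at 10.34 and 8.94 in 1 library and 7.46 and 6.49 in the other, with the neutrophil list at 10.18 and 5.88. At both ages the library with the higher B cell and T and NK cell lists was the one with the higher MHC class II list. Blood globins followed age in liver: Hbb-y was at 14.64 ± 1.61 at E10.25 and 8.31 ± 0.13 at P21, and Hbb-bs at 7.31 ± 1.11 and 15.20 ± 0.71.

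In the weighing of 3 patterns that follows, all tests except the splits of all libraries in this paragraph were chosen after the results were seen. In 100 splits of the same libraries with groups of the same sizes, the real one included, 1 gave as many genes as the real split for each of 8 comparisons. These were pMac against EMP (646, highest other 36), early Mac against pMac (1827, 636), brain (1013, 65), kidney (359, 47), liver (1037, 11), lung (335, 2) and skin (937, 2) at E14.5 to P21 and P21 against E14.5 (801, 186). Chance is unlikely there but not excluded, since 1 of 100 is the lowest share that these splits can show. The splits also treat all libraries as independent, which technical replicates would not be. For early liver 1 split also reached the real count (4, highest other 3), but with a margin of 1 gene, and 0 genes by limma in either sample set alone (761 and 689 at an unadjusted p under 0.05), chance stays open. For early brain 2 splits reached the real count (13, highest other 434) and for early yolk sac 3 did (18, 848), shares under 0.05, but other splits that call many more genes point to a structure of these libraries beyond tissue. For early limbs 12 splits did (1, 4), so chance cannot be excluded. A split of Mac and pMac called 636 genes, which may come from such structure or from a split close to the real stages, and this was not tested.

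The comparisons between stages overlap with the sample sets, since all pMac libraries are in the smaller set. The difference between the sets was measured within early Mac (9 smaller-set and 11 larger-set libraries), in the direction of the pMac against EMP calls. It had a median of 0.41 (quartiles 0.04 and 0.79) over the 646 genes, against 2.13 for the stage difference. Of the genes, 78.3% had the sign that a set difference would give. Genes at the floor in early Mac cannot show a set difference, so this test does not settle whether the sets are the whole source of this step. For early Mac against pMac the same measure was 0.28 with an upper quartile of 0.70, and 68.4% had that sign, which did not decide against 1.39. Within the smaller set alone, where the set cannot differ, 497 of 12192 genes passed, of which 456 are among the 1827. In 100 splits of its 9 Mac and 13 pMac libraries the highest other count was 3, which argues against the sets as the whole source of the step from pMac to early Mac. The macrophage core list, from which genes of sort markers were not left out, rose there by a median of 1.66, as the differentiation stage would need. Most pMac libraries are of E9.5 and all early Mac of E10.25 or E10.5, so age could give such a rise too. Age and stage were not separated in this test. The sets may still account for part of the calls, since 177 and 922 genes were called with the set as a covariate.

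Markers of tissue cells were high in some Mac libraries from each of the 5 tissues sampled from E14.5 on. In kidney at P21 the kidney epithelium list averaged 10.59 and the endothelium list was at 10.27 in 1 of 2 libraries. In brain the neural cell list averaged 8.76 at P8, and in 1 of 2 lung libraries of E18.5 the 2 measured lung epithelium genes averaged 10.91. These genes were not confined to lung, as they averaged 10.01 in 1 of 2 kidney libraries of E18.5 and up to 8.08 in brain at P21 and 7.90 in liver at P8. In kidney at E18.5 the alveolar macrophage list was at 6.12 and 8.98, and in lung at E18.5 at 5.93 and 9.56. At this age the list therefore did not separate the libraries by their tissue label. All of these libraries stayed in the tissue comparisons, and a mixture or exchange of libraries was not tested. From E12.5 to P21 in liver Mac, the change of Afp, the fetal albumin-like gene, minus that of Alb was -12.74, the direction of the switch in hepatocytes, which is consistent with RNA from hepatocytes in these libraries. All 12 keratinocyte genes measured were detected in both P21 skin libraries, with Krt14 at 16.60 ± 0.15, as RNA from keratinocytes would give. Genes at 14 or more in 1 tissue at P21, and near the floor in the others at P2, were higher in the other tissues at P21 than at P8 by a median of 0.39 (lower quartile 0.30, 23 genes, against 0.00 for 239 genes at 9 to 11), as a low share of reads exchanged between P21 libraries would give. A low share of a gene at 9 to 11 would mostly stay under the floor whatever its source, so those genes are no control. In the other tissues, the majority of the 23 genes were at the floor at P8 and so could not be lower at P21. Most of the 23 genes have liver as their source, with levels from the same 2 P21 libraries. Attached cells, free RNA, exchanged reads and transcription in the macrophages themselves were not tested against each other.

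Of the 226 genes lower in lung Mac, 156 were still called lower with the same number of highest transcripts in every library, and the median difference over the 226 genes was -2.13 against -2.14, which argues against the number of transcripts counted as the whole source. It leaves the scaling open: 70 genes were lower and 242 higher after centring on genes detected in most libraries, and 176 lower after centring on those detected in all. Without the libraries with few detected transcripts 0 genes were called in lung by limma (849 at an unadjusted p under 0.05), and those libraries include the only ones of P8 and P21, so the library and the age cannot be told apart. A candidate explanation left open is the age of the lung, since the alveolar macrophage list averaged 6.46 at E14.5 and 12.59 at P21 (n = 1).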
